A study of Mus musculus with 12 samples.

How the data were processed

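The series holds 12 libraries of 6 mouse embryonic stem cell lines, an early and a late S-phase library for each line. Per the labels' protocols, cells were labelled with bromodeoxyuridine for 2 h, stained with propidium iodide and sorted by flow cytometry, and DNA of 40000 cells per fraction was immunoprecipitated with an antibody to the label before library preparation. Bowtie2, SAMtools and bedtools and the genome build mm10 are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. The labels' treatment protocol names CRISPR for the rearrangements, and their breakpoints are not given there.

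The values used are a replication timing score that the authors deposited for 39094 positions of chromosome 1, spaced 5 kb apart, with 1 column per line that combines its early and late libraries. The deposited table is described by its submitters as quantile-treated and smoothed over 400 kb. The log base, the scale and the direction of the score are not given in the sources used here, and its values lie between -9.58 and 12.28. Higher was read as earlier by convention, and this was checked against gene density: the mean score of 1 Mb windows rose with their number of protein-coding genes in each line, with Spearman's rho across windows from 0.44 in Dbf to 0.70 in G4.WT. The interquartile range over chromosome 1 was 4.60 in all 6 lines, whereas the SD ran from 3.18 in G4.WT to 3.67 in Dbf, so the columns share a scale but not a distribution. No read count is in the table, so depth is unknown and no interval that needs it is given. Smoothing makes neighbouring positions dependent, so an SD over positions describes the shape of a region and not the error of its mean.

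Differences were computed as the rearranged line minus its wild-type control, position by position, with G4.WT as the control of DelB, DelBs and InvF and WT4Dbf that of Dbf. WT4Dbf minus G4.WT served as the measure of spread between samples. They were averaged over 74 to 79 Mb and over each 1 Mb window within it, and each mean was ranked by size among windows of equal length placed every 100 kb outside 72 to 81 Mb. A window of the locus that is partly missing was averaged over the positions it had and ranked among full windows, which is generous to short stretches. Windows of 1 Mb with a mean difference over 0.5 in size were counted along the chromosome, as were positions that crossed 0 with a difference over 0.5. Transitions were placed where a profile crosses 0, and a transition was matched to the nearest of the control within 500 kb. Transitions of the control without a match were left out of the counts, so large shifts may be more common than these counts show. The design assumed no replicates, and none were found, so no p-value was computed.

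Genes were placed with the RefSeq gene table of assembly GRCm38, the same build as mm10. A gene's value was the mean of the positions over its body or the nearest position within 50 kb, so genes deeper inside a stretch without values had none. Of 1204 protein-coding genes of chromosome 1, 1183 had a value in G4.WT. The genes named were fixed by rule before the data were examined: every measured gene of a locus list, and per comparison the 10 genes outside 72 to 81 Mb with the largest difference among those that differ in the same direction from both wild-type lines and whose difference from the assigned control exceeds that between the wild-type lines, however small the difference from the other wild-type line, at most 1 gene per 1 Mb. Some genes that meet this rule are not reported here. Members of the other lists are named as examples chosen after their values were seen. The lists, of locus genes, pluripotency-associated genes, developmental regulators, housekeeping genes, neuronal adhesion and synaptic genes, immune genes and feeder fibroblast genes, were also fixed beforehand, and some genes stand in more than 1 list. A list's median was ranked among 10000 random lists of equal size matched on the control's timing. Because locus genes are neighbours, they are not independent, and a random list of scattered genes varies less.

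Alternatives fixed beforehand changed the control line, the summary over positions, the centre of the profiles and the interval. They also changed the window size, the threshold and the background windows. Scaling to a common interquartile range was planned too, but that range was already equal in all lines. With centring it therefore only added a constant to each difference. Others were added after the data were seen: a threshold of 2, equal mean and SD of the profiles, the position at a gene's middle, gene lists on rescaled profiles, and intervals beside the missing stretches and in InvF. The code was checked on changes added to the G4.WT profile. Shifts of 3 and 1 in a 1 Mb window came back as 3 and 1 once the added noise was subtracted. Moving the whole profile by 100 kb moved its 119 transitions by 100 kb. Both outcomes were set by construction, so they check the arithmetic and do not measure how well real changes are recovered. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.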

Results

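Replication timing was measured along chromosome 1 in 6 lines of mouse embryonic stem cells, which are pluripotent cells derived from the early embryo. The assay, Repli-seq, labels newly made DNA with a nucleotide analogue, sorts cells from early and late S phase, and sequences the labelled DNA of each fraction, so that a locus copied early is enriched in the early fraction. G4.WT and WT4Dbf were taken as the unrearranged lines from their names. DelB, DelBs, InvF and Dbf were taken as rearranged lines from their names and the labels' mention of CRISPR. Each line had 1 early and 1 late library and 1 timing profile, in which higher values were read as earlier replication. The number of reads behind each value is unknown, because only the combined profile was used here. With 1 profile per line there was no replicate, so no test was made and no SD between replicates can be given. The difference between both wild-type lines stands in for that spread, but it comes from 1 pair and also holds any difference between those lines. The SDs given with differences are over 5 kb positions. Each percentile ranks the size of a difference among windows of chromosome 1 outside 72 to 81 Mb, which describes these libraries and is no p-value.

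In both wild-type lines the Epha4 locus held an early domain, a late domain and a smaller region of intermediate timing, in that order along the chromosome. Wnt6 and Wnt10a, which encode secreted signals of the WNT family, and Ihh, which encodes a hedgehog signal for the growing skeleton, lay in the early domain, at 5.86, 5.86 and 4.74 in G4.WT and 5.92, 5.99 and 4.04 in WT4Dbf. The early domain ended at 75.81 Mb in G4.WT and at 75.77 Mb in WT4Dbf, where the profiles crossed 0. From 76 to 77 Mb the mean timing was -5.29 ± 0.63 in G4.WT and -5.93 ± 0.48 in WT4Dbf (SD, n = 200 positions). Epha4, which encodes an ephrin receptor used in axon guidance and limb development, was at -0.63 in G4.WT and 1.28 in WT4Dbf, and Pax3, a transcription factor of neural crest and muscle progenitors, at 0.20 and -1.38.

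**Figure D1:**
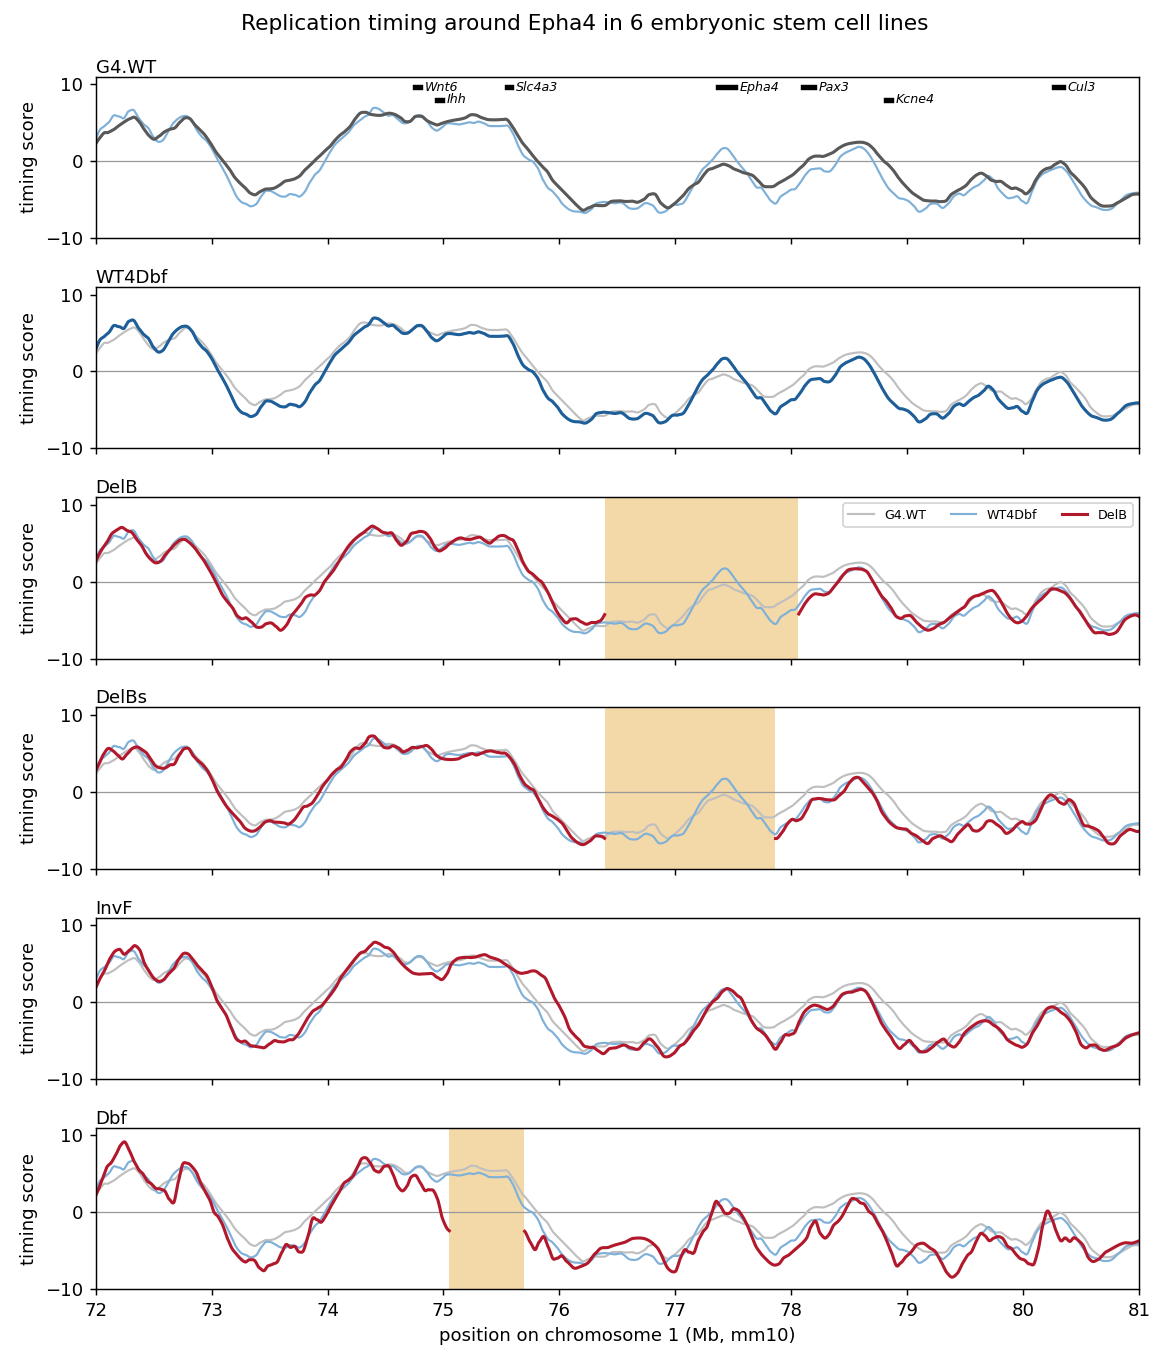
Timing score (vertical axis, no stated unit) at 5 kb positions from 72 to 81 Mb of chromosome 1 (mm10, horizontal axis), 1 panel per line, with G4.WT in grey and WT4Dbf in blue behind each rearranged line in red. Shaded stretches have no values in that line, and black bars mark genes (short genes are drawn 40 kb wide). InvF stays above 0 to 75.98 Mb, beyond the 75.81 Mb of G4.WT, and Dbf crosses 0 at 74.98 Mb.

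The wild-type lines were compared first, since they set the scale for every other difference. From 78 to 79 Mb WT4Dbf replicated later than G4.WT by a mean of -1.75 ± 0.65 (SD, n = 200 positions, percentile 97.2), and the genes there shifted together. Kcne4, a potassium channel subunit, differed by -2.87, Sgpp2, a sphingosine phosphatase, by -1.88, Pax3 by -1.58, Acsl3, a fatty acid activating enzyme, by -1.39 and Farsb, a subunit of a tRNA synthetase, by -1.11. Epha4 went the other way, with a difference of 1.91, while Wnt6 and Wnt10a differed by 0.06 and 0.13. In the early domain, Cnppd1, Abcb6, Atg9a, Stk16, Tuba4a, Dnajb2, Ptprn, Dnpep, Des, Speg, Obsl1, Inha, Stk11ip and Slc4a3 differed by -0.64 (Dnpep) to -1.07 (Ptprn). To the right of the locus, Serpine2 differed by -1.42, Ap1s3 by -1.10, Mrpl44 by -0.87, Cul3 by -0.60, Scg2 by -0.47 and Wdfy1 by -0.01. Over 74 to 79 Mb the mean difference was -0.74 ± 0.97 (SD, n = 1000 positions, percentile 89.6).

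Along the whole chromosome the wild-type lines also differed. Of 192 windows of 1 Mb, 28 were earlier and 59 later in WT4Dbf by over 0.5, and 5.21% of positions crossed 0 with a difference over 0.5, 3.87% from early to late and 1.34% from late to early. On profiles centred on their medians the windows were 38 and 55, and at equal mean and SD 47 and 40. Crossings of the median were 5.90% and 5.58%, but centring puts the same share of each profile above 0, so it nearly balances both directions by construction and says nothing about their balance. Equal means balance the differences over the chromosome likewise, so rescaled window counts give no reason for an excess in 1 direction. The SD of the difference over 183 windows outside 72 to 81 Mb was 0.69. Among the gene lists, 4 of 7 pluripotency-associated genes were earlier by over 0.5 and 1 was later, with a median of 0.53 (percentile 84.2 among 10000 random lists matched on timing). Prdm14, a regulator of the pluripotent state, differed by 2.60, Tfcp2l1 by 1.27 and Kdm5b by 1.24. Of 18 housekeeping genes 8 were earlier and 1 was later (median 0.42, percentile 94.9), and of 17 neuronal adhesion and synaptic genes 7 were earlier and 2 later (median 0.24, percentile 99.5), with Cntnap5a at 1.61 and Dpp10 at 1.37. Of the 30 genes of the locus list, 24 were later and 1 was earlier (median -0.81, percentile 0). Immune genes had a median of -0.42 (percentile 43.1), developmental regulators of -0.27 (percentile 75.07) and feeder fibroblast genes of -0.48 (percentile 26.9). Only the locus and neuronal lists lay outside the central 95% of random lists.

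The profiles of all lines were alike along the chromosome. Pearson's r across 38010 positions, which are not independent, had a median of 0.96 over 15 pairs of lines, from 0.87 for Dbf with G4.WT to 0.98 for DelB with WT4Dbf. G4.WT had a mean r of 0.94 with the other lines and Dbf of 0.91, while the means of DelB, DelBs, InvF and WT4Dbf were 0.96, 0.95, 0.96 and 0.96. The median score was -2.46 in G4.WT, -2.54 in WT4Dbf, -2.60 in InvF, -2.52 in Dbf, -2.73 in DelB and -3.00 in DelBs. Because the wild-type lines differed from each other, the main values against WT4Dbf are given beside those against G4.WT.

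DelB and DelBs were compared with G4.WT to see how timing stood around their deletions. In both lines the profile had no values over a stretch that began at 76395000 and held Epha4 as its only whole protein-coding gene. The stretch ran to 78060000 in DelB (1670 kb) and to 77860000 in DelBs (1470 kb). In the wild-type lines the stretch missing from DelB had a mean timing of -3.29 (G4.WT) and -3.65 (WT4Dbf), so the stretch without values replicated mainly late in them. To its left the early domain ended at 75.84 Mb in DelB and 75.79 Mb in DelBs, shifts of 33.5 kb and -23.4 kb from the end in G4.WT. Of the matched transitions elsewhere, 70 of 108 and 75 of 104 differed by at least as much. From the end in WT4Dbf the shifts were 77.7 kb in DelB, which 11 of 133 matched transitions reached, and 20.7 kb in DelBs, which 74 of 126 reached.

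To the right of the stretch without values, replication was later than in G4.WT in both deletion lines. The window that differed most in DelBs was 77 to 78 Mb, where 28 positions had values and the mean difference was -2.45 ± 0.48 (SD, percentile 100 among full windows), against -0.50 from WT4Dbf. From 78 to 79 Mb the mean difference was -1.87 ± 0.69 in DelB (SD, n = 188 positions, percentile 98.8) and -1.99 ± 0.70 in DelBs (SD, n = 200 positions, percentile 99.3). Pax3 differed by -2.45 in DelB and -2.00 in DelBs, Sgpp2 by -1.96 and -2.14, Kcne4 by -2.30 and -3.22, Acsl3 by -1.40 and -1.79, and Farsb by -1.10 and -1.89. WT4Dbf differed from G4.WT by -1.75 in the same window, and against WT4Dbf the means were -0.13 in DelB and -0.25 in DelBs. Against WT4Dbf, Pax3 differed by -0.88 in DelB and -0.42 in DelBs, Sgpp2 by -0.08 and -0.26, Kcne4 by 0.58 and -0.34, Acsl3 by 0.00 and -0.40, and Farsb by 0.01 and -0.79. The later timing right of the deletions was thus of the size found between the wild-type lines.

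Farther right lay another late stretch, with a mean timing of -3.62 from 79 to 80 Mb in G4.WT, where the deletion lines parted. Ap1s3, a subunit of an adaptor complex for vesicle transport, differed from G4.WT by 0.03 in DelB and -3.05 in DelBs, Wdfy1 by 1.16 and -1.44, Mrpl44 by 0.70 and -1.70, Serpine2, a protease inhibitor, by -0.28 and -2.14, Scg2 by -0.09 and -1.67, and Cul3 by -0.87 and -0.90. Against WT4Dbf, Ap1s3 differed by 1.14 in DelB and -1.95 in DelBs, Wdfy1 by 1.17 and -1.43, and Mrpl44 by 1.56 and -0.83. Serpine2 differed by 1.14 and -0.72, Scg2 by 0.38 and -1.20, and Cul3 by -0.27 and -0.30. Cul3 lies beyond 80 Mb, outside that stretch, and there the deletion lines did not part.

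To the left, Wnt6 differed from G4.WT by 0.60 in DelB and -0.11 in DelBs, Wnt10a by 0.69 and 0.00, and Ihh by -0.66 and -0.14. The genes from Cnppd1 to Slc4a3 lay between -0.52 (Dnajb2) and 0.58 (Inha) in DelB and between -1.11 (Ptprn) and -0.09 (Speg) in DelBs. Against WT4Dbf they lay between 0.44 (Tuba4a) and 1.41 (Inha) in DelB and between -0.39 (Cnppd1) and 0.71 (Speg) in DelBs. Ihh then differed by 0.05 in DelB and 0.57 in DelBs. From 75 to 76 Mb the mean difference was 0.07 ± 0.44 in DelB (SD, n = 200 positions, percentile 10.3) and -0.75 ± 0.36 in DelBs (SD, n = 200 positions, percentile 73.7). Against WT4Dbf those means were 1.02 in DelB (percentile 99.2) and 0.20 in DelBs (percentile 31.5). Over 74 to 79 Mb the mean difference from G4.WT was -0.44 ± 1.09 in DelB (SD, n = 666 positions, percentile 75.8), against 0.49 from WT4Dbf (percentile 98.7), and -0.89 ± 1.004 in DelBs (SD, n = 706 positions, percentile 93.5), against 0.10 from WT4Dbf (percentile 23.6). The sign of the 5 Mb mean therefore depended on which wild-type line was the control.

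Both names point to related deletions, so DelB was also set against DelBs. DelB was earlier by 0.82 ± 0.54 from 75 to 76 Mb (SD, n = 200 positions, percentile 94.2) and by 0.77 ± 0.78 from 76 to 77 Mb (SD, n = 78 positions, percentile 92.8). From 74 to 75 Mb and from 78 to 79 Mb the lines differed by -0.03 and 0.12.

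Along the whole chromosome 9 windows were earlier and 56 later in DelB than in G4.WT, of 188, and 11 and 68 of 190 in DelBs. Against WT4Dbf the counts were 9 and 20 in DelB and 13 and 49 in DelBs. On centred profiles 33 were earlier and 29 later in DelB, and 51 earlier and 23 later in DelBs, and at equal mean and SD 32 and 34 in DelB and 31 and 30 in DelBs. Positions that crossed 0 made up 5.30% in DelB and 5.52% in DelBs against G4.WT, and 1.75% and 2.77% against WT4Dbf. Against G4.WT, 4.40% and 4.90% went from early to late and 0.90% and 0.62% from late to early. On centred profiles, whose balance is set by construction, 4.33% and 3.95% crossed in DelB and 3.54% and 3.42% in DelBs. In DelB the genes with the largest differences from G4.WT were Fbxo36 at 3.01, Cr1l at -2.97, Mrpl15 at 2.92, Atp1b1 at 2.91, F11r at 2.54, Trmt1l at 2.503, Mr1 at -2.49, Aspm at 2.35, Mark1 at -2.33 and Enah at 2.30. Atp1b1, a subunit of the sodium pump, and Mark1, a microtubule-associated kinase, also differed from WT4Dbf by 2.79 and -2.28, while the other 8 differed from it by less than 1. In DelBs they included Apcs at -3.57, Rgs20 at 3.01, Rbm44 at -2.90, Cep350 at -2.79, Adam23 at 2.75, Syt14 at -2.64, Stau2 at -2.62, Uap1 at -2.57 and Rpe at -2.52. Rpe, an enzyme of the pentose phosphate pathway, differed by -2.92 from WT4Dbf as well, followed by Adam23 at 1.41, Apcs at -1.33 and Rgs20 at 1.196.

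Of the 29 measured genes of the locus list, 6 were earlier and 8 later in DelB than in G4.WT (median -0.23, percentile 10.2), and 0 were earlier and 21 later in DelBs (median -1.06, percentile 0). Against WT4Dbf the medians were 0.55 in DelB (18 earlier, 1 later, percentile 99.98) and -0.26 in DelBs (2 earlier, 6 later, percentile 2.5), and on centred profiles the median in DelB was 0.04. Pluripotency-associated genes had medians of 0.72 in DelB (5 of 7 earlier, 1 later, percentile 82.6) and 0.19 in DelBs (3 earlier, 1 later, percentile 78.7), and Prdm14 differed by 2.02 and 1.28. Of 18 housekeeping genes 9 were earlier and 1 later in DelB (median 0.50, percentile 95.8), with Sf3b1 at 1.18, and 2 were earlier and 4 later in DelBs (median -0.15, percentile 42.4). Developmental regulators had a median of -0.66 in DelB (7 of 29 earlier, 15 later, percentile 5.8), with Prox1 at -2.12 and Hlx at -1.78, and of -0.34 in DelBs (percentile 80.3). Neuronal genes had medians of 0.07 (percentile 98.8) and -0.31 (percentile 90.9), immune genes of -0.35 (percentile 53.0) and -0.58 (percentile 45.9), and feeder fibroblast genes of -0.42 (percentile 25.6) and -0.28 (percentile 52.0). Against WT4Dbf the medians of housekeeping genes were -0.27 in DelB (percentile 5.67) and -0.83 in DelBs (0 of 18 earlier, 12 later, percentile 0.06), and those of neuronal genes -0.26 (percentile 3.63) and -0.56 (2 of 17 earlier, 10 later, percentile 0.18), so the neuronal medians ranked high against one wild-type line and low against the other. Pluripotency-associated genes were then at -0.18 and -0.46 (percentiles 24.4 and 40.5), developmental regulators at 0.13 and -0.13 (61.6 and 27.7), immune genes at 0.24 and 0.15 (85.5 and 83.8), and feeder fibroblast genes at -0.16 and -0.11 (18.9 and 25.7). On centred profiles the sign turned in DelBs for developmental regulators (0.20), housekeeping genes (0.39), neuronal genes (0.22) and feeder fibroblast genes (0.25), and at equal mean and SD for pluripotency-associated genes (-0.12) and neuronal genes (0.22).

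InvF was compared with G4.WT to see how timing stood in a line whose name and treatment point to an inversion. In reference coordinates the early domain reached farther in InvF. It ended at 75.98 Mb, 166 kb beyond its end in G4.WT and 210.3 kb beyond that in WT4Dbf. Breakpoints are not given, so the order of sequence in InvF may differ from the reference here. The shift then need not be a distance along its chromosome. Of the matched transitions elsewhere, 7 of 106 differed by as much from G4.WT and 5 of 129 from WT4Dbf. G4.WT had 114 transitions there and WT4Dbf 142, and those without a match were not counted. From 75700001 to 76100000, an interval chosen after its values were seen, InvF was at 1.47 ± 2.56 (SD, n = 80 positions), whereas G4.WT was at -1.60, WT4Dbf at -3.03, DelB at -1.79, DelBs at -2.36 and Dbf at -4.88. The mean difference was 3.07 ± 0.87 from G4.WT, which 6 of 1827 windows of 400 kb elsewhere reached, and 4.50 ± 0.91 from WT4Dbf, which 0 of 1827 reached. Within the early domain, which began at 73.88 Mb in G4.WT and 73.98 Mb in InvF, Wnt6 and Wnt10a were later in InvF, by -2.19 and -2.22 against G4.WT and by -2.25 and -2.35 against WT4Dbf, and Ihh by -1.57 and -0.86. Over 74700001 to 75100000, which holds these genes and was also chosen late, the mean difference from G4.WT was -1.51. Of 1827 windows elsewhere 294 reached it. From WT4Dbf it was -1.24, which 43 of 1827 reached. In the planned window from 74 to 75 Mb the means were -0.37 (percentile 29.6) and -0.11 (percentile 20.1). Between Ihh and the end of the domain, the genes from Cnppd1 to Slc4a3 differed from G4.WT by -0.63 (Slc4a3) to 0.65 (Des). From WT4Dbf they differed by 0.09 (Slc4a3) to 1.33 (Des). Nhej1, between Ihh and Cnppd1, differed by -0.89 from G4.WT and -0.45 from WT4Dbf.

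In the windows fixed before the data were examined, InvF differed from G4.WT by 1.06 ± 1.68 from 75 to 76 Mb (SD, n = 200 positions, percentile 78.3) and from WT4Dbf by 2.01 ± 2.00 (SD, n = 200 positions, percentile 99.9). The window that differed most from G4.WT was 78 to 79 Mb, with -1.84 ± 0.98 (SD, n = 200 positions, percentile 96.4), but against WT4Dbf it differed by -0.09. Epha4 itself was at 1.41 in InvF, earlier than G4.WT by 2.04 and than WT4Dbf by 0.13. Over 74 to 79 Mb the mean difference was -0.32 ± 1.59 from G4.WT (SD, n = 1000 positions, percentile 41.9) and 0.42 from WT4Dbf (percentile 92.9).

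**Figure D2:**
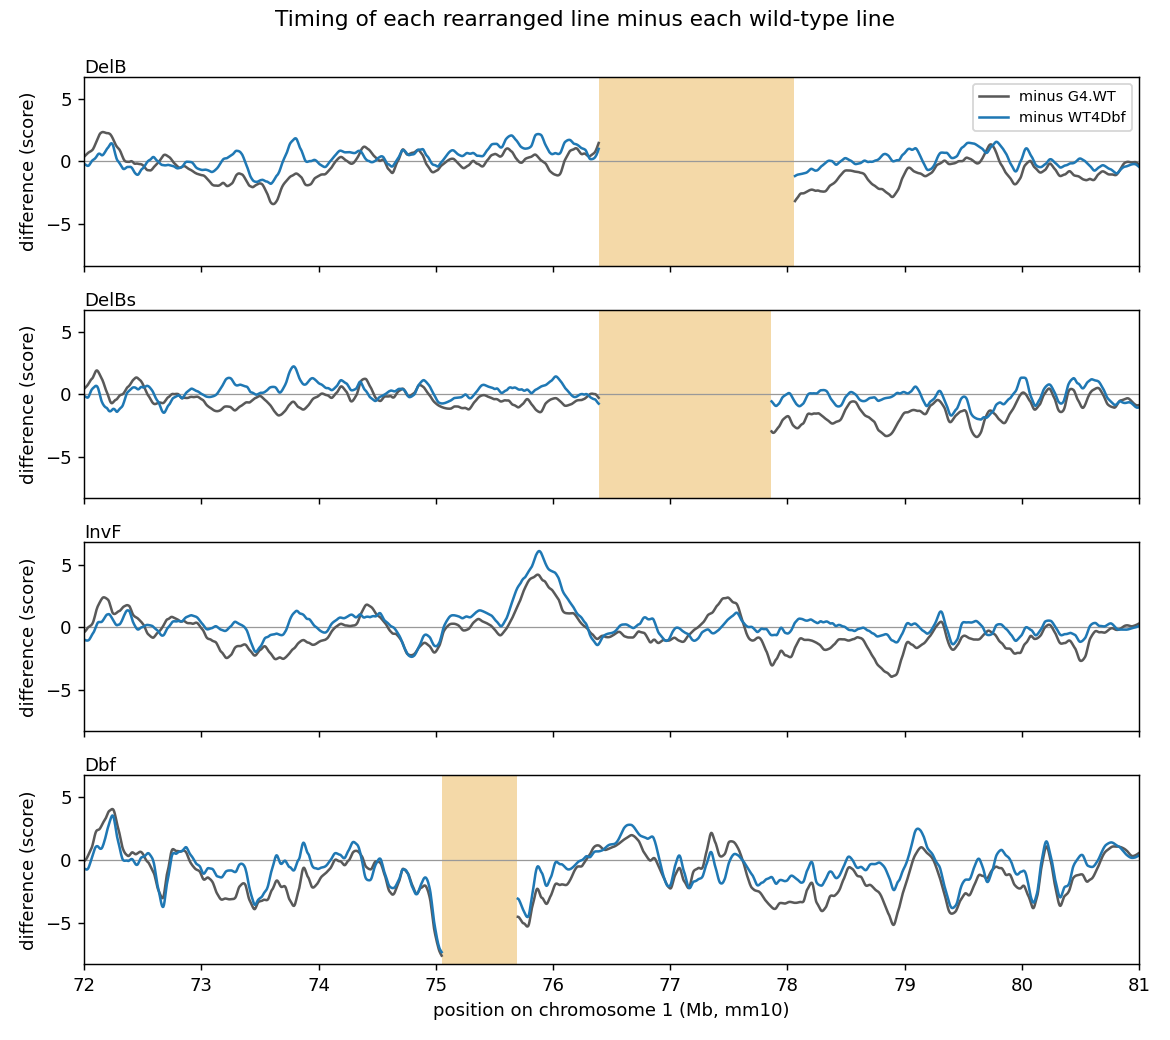
Timing of each rearranged line minus G4.WT (grey) and minus WT4Dbf (blue), in score (vertical axis), at 5 kb positions from 72 to 81 Mb of chromosome 1 (mm10, horizontal axis), with stretches that have no values shaded. In InvF both curves peak from 75700001 to 76100000, where the means are 3.07 and 4.50, and from 78 to 79 Mb the curves of DelB, DelBs and InvF against WT4Dbf lie near 0.

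Along the chromosome 36 windows were earlier and 80 later in InvF than in G4.WT, of 192, and 13 and 29 against WT4Dbf. On centred profiles 43 were earlier and 70 later than in G4.WT, and at equal mean and SD 51 and 45. Positions that crossed 0 made up 5.61%, 4.84% from early to late and 0.77% from late to early, and on centred profiles, balanced by construction, 7.48% and 7.55%. The genes that differed most from G4.WT were Prox1 at -3.47, Apcs at -3.19, Ccdc185 at -3.10, Trmt1l at 3.07, Kdsr at -2.96, Nos1ap at -2.96, Aff3 at -2.79, Prdm14 at 2.74, Tmcc2 at 2.64 and Stau2 at -2.62. Against WT4Dbf, Trmt1l, a tRNA methyltransferase-like protein, differed by 1.48, Tmcc2 by 1.47, Kdsr, an enzyme of sphingolipid synthesis, by -1.44, Aff3 by -1.35 and Prox1, a transcription factor of lymphatic development, by -1.198, and Prdm14 by 0.14. Of 30 developmental regulators 5 were earlier and 20 later (median -1.27, percentile 0.35), with Tfap2b at -1.86 and Gli2 at 1.21. Of 18 housekeeping genes 11 were earlier and 2 later (median 0.77, percentile 99.3), led by Ncl at 2.35 and Xrcc5 at 1.63, and of 17 neuronal genes 7 were earlier and 4 later (median 0.32, percentile 100). Of the 30 locus genes 2 were earlier and 16 later (median -0.58, percentile 0.06). Against WT4Dbf the medians of these lists were -0.26, -0.06, 0.14 and 0.27 in the same order (percentiles 16.6, 8.85, 97.05 and 96.8). Pluripotency-associated genes had a median of 1.198 (5 of 7 earlier, percentile 92.8), immune genes of -0.29 (percentile 91.6) and feeder fibroblast genes of -0.44 (percentile 37.5). Against WT4Dbf these were 0.24 (1 of 7 earlier, percentile 35.3), 0.21 (6 of 25 earlier, 7 later, percentile 98.8) and 0.09 (percentile 67.8).

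Dbf was compared with WT4Dbf, whose name ties it to Dbf. Dbf had no values from 75055000 to 75695000 (645 kb), a stretch that held 25 protein-coding genes whole, among them Des, the muscle intermediate filament desmin, Inha, a subunit of the hormone inhibin, and Slc4a3, an anion exchanger. It lay in the early domain, with a mean timing of 4.35 in WT4Dbf and 5.16 in G4.WT. Beside it Dbf replicated later: over the 400 kb on the left the mean difference from WT4Dbf was -2.66 ± 1.91 (SD, n = 80 positions, percentile 98.1) and over the 400 kb on the right -1.88 ± 1.47 (SD, n = 80 positions, percentile 93.3), both intervals chosen after the gap was seen. Ihh differed by -2.49, Wnt10a by -2.14 and Wnt6 by -1.38, and Nhej1, a DNA repair gene that the gap reaches into, by -5.99 over the 17 of its 33 positions that have values in both lines.

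The early domain ended at 74.98 Mb in Dbf, a shift of -790.5 kb from its end in WT4Dbf, of which 645 kb had no values. The remaining shift of -145.5 kb was reached by 13 of 122 matched transitions elsewhere, and that from G4.WT, -189.6 kb, by 5 of 102. WT4Dbf had 142 transitions there and G4.WT 114, and those without a match were not counted. The full shift of -790.5 kb depended on the crossing level. At the chromosome 1 median of each profile the domain ended at 75.704 Mb in Dbf and 75.863 Mb in WT4Dbf. Both ends then lay right of the 645 kb without values. The end in Dbf was still left of that in WT4Dbf, by a distance similar to the remaining shift of -145.5 kb. From 75 to 76 Mb the mean difference was -3.00 ± 2.00 (SD, n = 71 positions, percentile 99.7), and over 74 to 79 Mb it was -0.74 ± 1.52 (SD, n = 871 positions, percentile 85.2). Farther from the gap Epha4 differed by -0.996 and Pax3 by -1.18. Against G4.WT they differed by 0.92 and -2.75, so the sign at Epha4 depended on the control. Of the 16 measured locus genes, 12 were later and 1 was earlier (median -1.09, percentile 2.01).

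Dbf differed widely from WT4Dbf along the whole chromosome, with 43 windows earlier and 69 later of 191 and 5.68% of positions crossing 0, 3.75% from early to late and 1.92% from late to early. At equal mean and SD 50 windows were earlier and 58 later, and on centred profiles, balanced by construction, 7.57% and 7.83% of positions crossed. Its adjacent positions also differed most, by a median of 0.06 against 0.03 in G4.WT. The genes that differed most included Gpr161, a receptor that restrains hedgehog signalling, at -5.96, Sec16b at 5.51, Ccdc150 at 4.65, Pigc at -4.34, Serpinb3d at 4.32, Zfp281, a zinc finger protein of pluripotent cells, at 4.22, Stat4, a cytokine signalling factor, at -3.31, Ino80d at 3.12 and Eya1 at -3.07. Against G4.WT these genes differed in the same direction, by the rule that named them, with Gpr161 at -5.10 and Ccdc150 at 4.81. Immune genes had a median difference of 0.24 (8 of 25 earlier, 9 later, percentile 96.0), neuronal genes of 0.13 (percentile 92.9), feeder fibroblast genes of 0.15 (percentile 88.8), pluripotency-associated genes of 0.41 (percentile 54.7), developmental regulators of -0.59 (6 of 30 earlier, 16 later, percentile 19.2) and housekeeping genes of -0.03 (percentile 58.9). Against G4.WT the median of the locus genes was -2.04 (1 of 16 earlier, 15 later, percentile 0.14), that of pluripotency-associated genes 1.35 (percentile 83.4), developmental regulators -1.14 (percentile 17.2), housekeeping genes 0.69 (percentile 97), neuronal genes -0.0077 (percentile 98.0), immune genes -0.36 (percentile 88.5) and feeder fibroblast genes 0.21 (percentile 94.95).

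**Figure D3:**
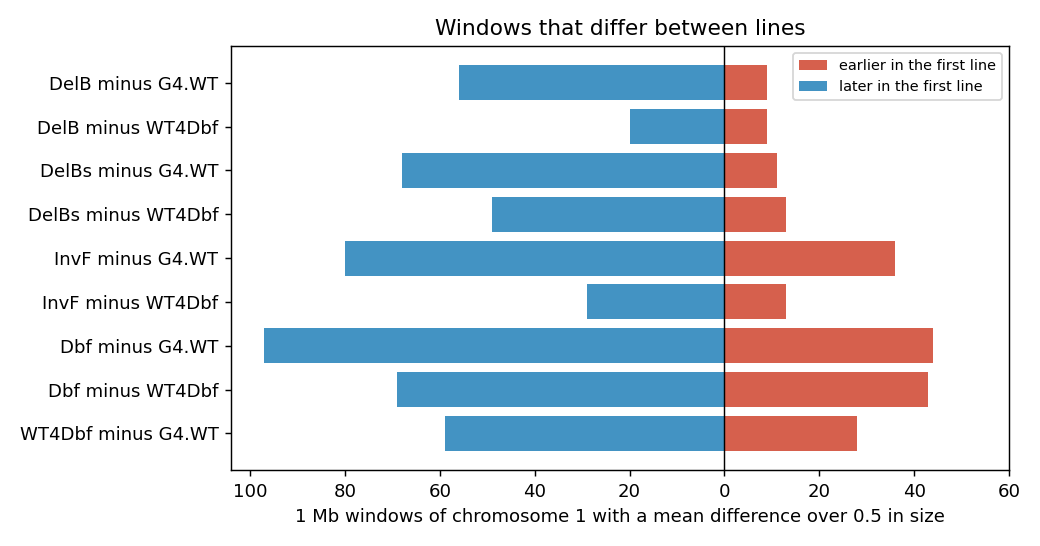
Number of 1 Mb windows of chromosome 1 (horizontal axis) whose mean timing differs by over 0.5, for each pair of lines (vertical axis), with windows earlier in the first line in red to the right and later ones in blue to the left. Against G4.WT, DelB has 56 later windows and InvF 80, and against WT4Dbf 20 and 29, while WT4Dbf itself has 59 against G4.WT.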

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

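The flank intervals, the InvF intervals, the threshold of 2 and equal mean and SD were chosen after seeing the data. So were the position at a gene's middle and gene lists on centred profiles. The other settings were fixed before, and the value at each gene's transcription start was not run because the gene table gives no strand. Of the alternatives to values that answer a comparison, 91 moved by less than the wild-type SD or, for counts, by less than 1.5 times. A further 54 moved farther and 2 with a main value over 0.5 in size changed sign. Of the others 208 stayed, 16 moved and 7 changed sign. For differences the wild-type SD of 0.69 is a lenient bound. Over 1 Mb windows DelB and InvF minus WT4Dbf had SDs of only 0.35 and 0.40. With main values under 0.5 counted too, 12 and 29 changed sign. Centred and scaled profiles supplied 24 of the 91 and 47 of the 208. That setting added only a constant below the wild-type SD to each difference. It could not move differences farther than that SD, so for them these labels show no robustness. The cause was not tested unless stated. With the other wild-type line as control the 74 to 79 Mb mean became 0.49 in DelB, 0.10 in DelBs, 0.42 in InvF and -1.47 in Dbf, of which DelB, DelBs and InvF changed sign, and the window that was largest against the assigned control became -0.13, -0.50, -0.092 and -4.20. The 75 to 76 Mb window of DelBs became 0.20. Windows over 0.5 became 29 in DelB and 42 in InvF, and crossings 1.75%, 2.77% and 2.43% in DelB, DelBs and InvF. List medians over 0.5 in size turned to -0.18 (pluripotency-associated), 0.13 (developmental) and -0.27 (housekeeping) in DelB, 0.15 (immune) in DelBs, and 0.27 (locus) and -0.059 (housekeeping) in InvF; smaller ones turned to 0.55 (locus), -0.26 (neuronal) and 0.24 (immune) in DelB, -0.46 (pluripotency-associated) in DelBs, 0.21 (immune) and 0.09 (feeder fibroblast) in InvF, and 0.69 (housekeeping), -0.0077 (neuronal) and -0.36 (immune) in Dbf. With the same sign, locus genes moved to -0.26 in DelBs and -2.04 in Dbf, pluripotency-associated genes to 0.24 in InvF and 1.35 in Dbf, and developmental regulators to -0.26 in InvF. Right of the stretch without values Dbf gave -3.31, DelB -0.51 and DelBs -0.37, and the InvF interval from 75700001 to 76100000 gave 4.50. With the mean of both wild-type lines that window was -0.9996 in DelB, -1.48 in DelBs and -0.97 in InvF. With the median of the other 5 lines it was -0.10, -0.29, -0.0094 and -4.04 in DelB, DelBs, InvF and Dbf, and 0.12 in WT4Dbf, which turned; the DelB locus mean was 0.29, the right flanks were -3.14 in Dbf, -0.58 in DelB and -0.28 in DelBs, and the InvF interval 3.98. Of 76 to 78 Mb DelB has values only at the 78 positions of its 76 to 77 Mb window, with a mean of 0.33, and 2 Mb windows gave -0.97 in DelBs and -1.45 in Dbf. For DelB, DelBs, InvF, Dbf and WT4Dbf, in that order, windows numbered 20, 25, 41, 50 and 23 over a threshold of 1; 2, 0, 2, 2 and 3 over a threshold of 2, which by construction can only lower the counts; and 173, 199, 248, 247 and 207 at 0.5 Mb, where there are more windows to count. On centred profiles crossings became 8.28% in DelB, 15.03% in InvF, 15.4% in Dbf and 11.5% in WT4Dbf, with a crossing level in the late range, where more positions lie. At that level the early domain ended at 75.704 Mb in Dbf, 75.863 Mb in WT4Dbf, 75.92 Mb in DelBs, 75.94 Mb in G4.WT and 76.06 Mb in InvF. At equal mean and SD the left flank of DelBs was 0.27. Depth is unknown, so its effect on any value could not be assessed.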

Other observations

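The tests of Dbf and InvF below were chosen after the results were seen, and the tests of G4.WT and of the shared control were written before. At the left end of its stretch without values Dbf stood at -2.40 and at its right end at -2.46, so its profile differed by -0.06 across the stretch, whereas WT4Dbf differed by -4.32 between those positions. In DelB and DelBs the profiles differed by 0.09 and -0.03 across theirs, against 4.72 and 2.65 in G4.WT and 2.26 and -0.22 in WT4Dbf at the same positions, so a step near 0 was also found in an unrearranged line for DelBs. Each line was also scanned for runs of positions that lay outside the range of all other lines by over 1. The first-ranked run of InvF by size times length, among 36, was 75675001 to 76100000, inside the locus and with no protein-coding gene, and the first-ranked run of Dbf, among 384, was 53790001 to 54535000, around Hecw2, Ccdc150 and Pgap1. Runs of G4.WT numbered 178, the first of which lay at 155095001 to 156050000, around Stx6, Xpr1, Lhx4 and Cep350. Those of DelB, WT4Dbf and DelBs numbered 12, 32 and 58. Inside the locus G4.WT was earlier than all other lines with values at 77780001 to 78095000 and at 78650001 to 78995000, around Acsl3 and Kcne4. Dbf was later than all others beside its stretch without values, at 74930001 to 75050000 and 75695001 to 75850000.

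Beside its stretch without values Dbf replicated later than WT4Dbf, by -2.66 over the 400 kb on the left. Unequal scale was argued against, since profiles set to equal mean and SD gave -2.72. Noise of the Dbf profile stayed open, as the difference ranked at percentile 98.14 of windows elsewhere, below the bound of 99, although both sides joined (400 kb in all) ranked at 98.9 against WT4Dbf and 99.6 against the median of the other lines. Smoothing that joins both sides of the stretch was not settled either. From 200 to 400 kb to the left the mean was still -1.65, at a percentile of only 83.0. That rank does not show that the difference ends there, nor that it stands out from noise. From 200 to 400 kb to the right the mean was -0.94 against WT4Dbf (percentile 56.8). Against the median of the other lines it was -2.22 (percentile 93.6). If the stretch without values was deleted in Dbf, a change of timing brought about by its loss is a further hypothesis. No breakpoint is given, this was not tested, and 1 profile cannot separate it from noise and smoothing.

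From 75700001 to 76100000 InvF replicated earlier than every other line, by 3.07 relative to G4.WT, the earliest of them, so a change confined to the control was argued against. Unequal scale was argued against as well, with a difference from WT4Dbf of 4.49 at equal mean and SD. Because the interval was picked for its values, noise was tested by the largest 400 kb difference within 74 to 79 Mb, which was 3.98 from the median of the other lines, against at most 1.79 in 36 other 5 Mb stretches, and 4.50 from WT4Dbf, against at most 2.61, so noise of the size found elsewhere in the profile was argued against. Against G4.WT 1 of 36 stretches was as large (3.76, a share of 0.054 with the locus counted, over the bound of 0.05 first set for each of these controls), but from the median of the others it was at most 1.79 and so no deviation of InvF alone, and noise peculiar to the locus stays open without a replicate. A candidate explanation is that the inversion set a late stretch beside the early domain and an early one, with Wnt6 and Wnt10a, beside late sequence. The breakpoints were not used here and this was not tested. Wnt6 and Wnt10a were also later in Dbf than in WT4Dbf, by -1.38 and -2.14, so later timing at these genes was not particular to InvF.

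G4.WT stood apart from the other lines, though less than Dbf: over 1 Mb windows the deviation from the median of the others had an SD of 0.65 in G4.WT and 0.88 in Dbf, against 0.27 to 0.44 in the rest. WT4Dbf minus G4.WT had an SD of 0.69, and DelB, InvF, DelBs and Dbf minus WT4Dbf had 0.35, 0.40, 0.50 and 0.85. Stronger smoothing and a narrower scale of G4.WT were each argued against as the whole cause: smoothing WT4Dbf to the same roughness left the SD at 0.687 (0.666 at the lowest, over kernels of up to 1000 kb), and the residuals of a straight-line fit had an SD of 0.697. The covariance of DelB and DelBs differences from G4.WT was 0.234 (r = 0.73), below the 0.327 of DelB and WT4Dbf differences. The shared control may thus carry what DelB and DelBs differences have in common. With separate wild-type controls r was -0.34. The difference between the wild-type lines lowers that value by construction, so it is no neutral check of what DelB and DelBs share. Simulated unchanged lines with a common control gave r = 0.50, but at equal noise. The SD of the deviation above was 0.65 in G4.WT, 0.27 in DelB and 0.44 in DelBs, so the simulated r was no benchmark for 0.73. A clone, passage or culture difference of G4.WT was not tested, and no biological explanation was tested.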
